A study of Arabidopsis thaliana with 12 samples.

How the data were processed

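Transcript levels were measured in 12 samples of Arabidopsis thaliana with 1-colour Affymetrix ATH1 arrays, 1 array per sample. Per the labels, mature rosette leaves (growth stage 3.90) and flowers (growth stage 6.90) were taken from wild-type Landsberg erecta plants and from plants carrying the lug-3 allele in the same background, with 3 samples in each of the 4 groups. The labels' protocols describe a pool of 20 plants per sample, 4 days of seeds at 4 °C and growth at 20 °C under constant conditions. They do not say whether the 3 pools of a group were grown and extracted separately, so the p-values measure only the spread between these samples, which may be technical.

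The deposited table holds probe set intensity on a linear scale, called signal in the text, as the authors made it. MAS5 and GCOS are named in the submitters' processing notes, and their versions and other upstream settings are not given in the sources used here. The values show that each array had been scaled by the authors: the mean signal after trimming 2% of the probe sets at each end was 100.0 on every array. No further scaling was applied, because the deposited intensity values were already on a common scale. On each array 3.81% to 5.73% of the probe sets had a signal below 1. The number of arrays limits the precision.

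The array held 22810 probe sets. The 64 control probe sets were left out of the tests, leaving 22746. GEO's platform annotation listed 14016 of them, 13513 with 1 gene and 503 with several, and 8730 are unnamed here. Of the probe sets with 1 gene, 13436 were matched through their Entrez ID to a RefSeq gene table for current symbols and 77 kept the name in the annotation, giving 13355 different loci. No gene was named from a probe set with several genes. No coordinates are printed, and the gene table served for names and for the order of genes along the chromosomes.

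Signals were transformed as log2(signal + 8), where 8 is the rounded 20th percentile of all signals. A log2 change is therefore on the log2(signal + pseudocount) scale and understates the change of genes with low signal. A probe set was tested when its signal was above 16.4, the pooled 30th percentile, on at least 3 of the 12 arrays, which left 17877. A single linear model with 4 group means was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, without trend or robust options). The fit had 8 residual and 3.79 prior degrees of freedom. The contrasts tested were lug-3 against wild type in leaves, the same in flowers, wild-type flowers against wild-type leaves, and the difference between the lug-3 change in flowers and that in leaves (the interaction). A probe set was called at a Benjamini-Hochberg adjusted p below 0.05. Unless another setting is named beside it, an adjusted p of a gene comes from this limma fit.

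Calls shared by the leaf and flower comparisons were set against the product of the numbers of calls divided by the number tested, with Fisher's exact test. Those comparisons share no array, but both use the same estimate of the spread of each probe set. Their calls are therefore not independent, and the chance numbers and Fisher p-values are only a guide. Of 20 gene lists fixed before the data were examined, with 397 different loci, 64 loci had a named probe set and 56 were tested. List genes called measured below are tested ones only, and other genes of a list may have probe sets unnamed here. The 12 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. A gene with several probe sets was represented by the probe set of highest mean signal.

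The genes named were chosen by a rule fixed before the data were examined. For each lug-3 comparison it takes the 10 largest rises and the 10 largest falls among called probe sets with 1 gene whose 3 lug-3 arrays all lie on the same side of the 3 wild-type arrays. For the tissue contrast it takes the 5 largest each way by the same rule, and for the interaction the 5 largest each way among calls with 1 gene. It adds LUG, LUH, SEU and AG and up to 4 genes of each list with the smallest p. LUG, LUH and AG have no probe set named here, so their transcripts were not analysed here. Genes named from families, from the stretch of chromosome 4 or as examples of a shared call were chosen after their values were seen.

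After the data were examined, 24 families with at least 8 tested genes were formed from shared symbol stems and tested with camera in the same way. The stem GH was separated into glycosyl hydrolase family 9 and the GH3 enzymes after its values had been seen. Also after the data were examined, the ratio of signals from the 3' and 5' control probe sets of GAPDH, a measure of RNA quality, was added as a covariate, and the fit was repeated without the 3 arrays of highest ratio. These were wild-type leaves 2 and 3 and lug-3 flowers 3, so wild-type leaves 1 alone then stood for wild type in leaves. The other groups gave the spread for the leaf values of that fit.

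The alternatives fixed before the data were examined were pseudocounts of 1 and 32, no filter and a filter at the 50th percentile (44.7), quantile normalization, centring of each array on its median, fits to the compared groups alone, robust and trend options of eBayes, array weights, the replicate number as a block, an adjusted p below 0.01, and leaving out each array in turn. The scripts were tested on simulated data for the same 17877 probe sets. With 100 probe sets changed at each size, the leaf contrast recovered 69 at a log2 change of 1 and 97 at a log2 change of 2. The flower contrast recovered 68 and 96, the tissue contrast 65 and 93, and the interaction 36 and 88. There were 10 false calls in leaves, 10 in flowers, 9 for tissue and 11 for the interaction. In 100 simulated rounds of camera, run for the leaf contrast on 9902 genes, the changed set was called in 100 and another of the 20 sets in 7. Simulated genes varied independently, while the correlation estimated within the anthocyanin list was 0.90, so these rates need not hold for the lists. Far fewer probe sets were changed in the simulations than were called in the data. A planted cluster of 15 calls among 200 neighbours in a single row of genes was found in 100 of 100 rounds. That is the size seen in the data, so this rate says nothing about smaller clusters.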

Results

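The series measured transcript levels in mature rosette leaves and in flowers of wild-type Landsberg erecta plants and of lug-3 mutants, with 3 arrays in each of the 4 groups and a pool of 20 plants behind each array. LEUNIG (LUG), the gene altered in lug-3, encodes a transcriptional corepressor known for keeping the carpel and stamen identity gene AGAMOUS out of the outer floral organs. The title of the series names genes regulated by LUG as its subject. Arrays were scaled by the authors, and the median signal lay between 38.3 and 41.0 on leaf arrays and between 48.8 and 52.5 on flower arrays. Spearman's rho between arrays of a group, across probe sets, was 0.950 to 0.985. No probe set is named for LUG here, so the LUG transcript was not analysed here and gives no check of the labels.

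RNA quality, measured as the ratio of the 3' to the 5' GAPDH control signal, was uneven in the leaf samples. It was 2.66 ± 0.877 (SD, n = 3) in wild-type leaves and 1.58 ± 0.102 in lug-3 leaves, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. In flowers the ratio was 1.83 ± 0.227 in wild type and 2.26 ± 0.754 in lug-3 (exact permutation p = 0.6). The ratio for actin was 4.43 ± 1.39 in wild-type and 2.42 ± 0.188 in lug-3 leaves (exact permutation p = 0.1). The ratio for ubiquitin was 1.90 ± 0.415 and 1.60 ± 0.115 (exact permutation p = 0.4), with lug-3 leaves 1 (1.72) above wild-type leaves 1 (1.43). The highest GAPDH ratios were those of wild-type leaves 3 (3.44), lug-3 flowers 3 (3.10) and wild-type leaves 2 (2.83).

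The first comparison asked which transcripts change in rosette leaves when LUG is impaired. Acid phosphatase and pectin methylesterase genes were among the largest rises in lug-3 leaves, and the anthocyanin gene AT4G14090 was among the largest falls. The transcript of AT5G44020, an acid phosphatase family gene, rose from a signal of 40.2 ± 13.7 to 382 ± 163 (log2 change 2.94, SE 0.310, adjusted p = 0.000135). ATPMEPCRB and AT3G10720, both pectin methylesterase genes, rose by 2.70 and 2.47 on the log2 scale. AT4G14090, which encodes the anthocyanin 5-O-glucosyltransferase UGT75C1, fell by 2.74 (102 ± 57.2 to 6.83 ± 2.69, adjusted p = 0.00259). In all, 3993 of 17877 probe sets were called, 2020 higher and 1973 lower in lug-3, of which 536 and 349 changed by more than 2-fold.

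Among the other large rises in leaves were AT2G10940, a proline-rich protein gene (log2 change 2.92, 189 ± 147 to 1130 ± 232), and AT3G54400, an aspartyl protease family gene (2.76, 15.6 ± 3.39 to 160 ± 60.9). AT2G20670 rose by 2.69 and AT2G34930, a leucine-rich repeat protein gene, by 2.62. AT1G31710, a copper amine oxidase gene, rose by 2.51. AT1G04040, of the same acid phosphatase family as AT5G44020, rose by 2.46 (57.4 ± 1.97 to 371 ± 132). AT4G23820, a pectin lyase-like gene, rose by 2.39. The adjusted p of these 7 genes was at most 0.005, that of AT2G20670, which lost its call with the GAPDH ratio as a covariate (1.82, adjusted p = 0.0682). The largest fall was that of AT4G18250, a receptor-like kinase gene, whose signal went from 81.2 ± 6.29 to 2.71 ± 1.75 (log2 change -3.07, adjusted p = 2.26e-05). AT4G19240 fell by 3.03 (136 ± 13.8 to 10.2 ± 5.41), AT1G64360 by 2.70 (2047 ± 193 to 315 ± 84.0), AT1G22160 by 2.62 and AT1G80130 by 2.61. AT5G39520 fell by 2.52, AT4G09760, a choline kinase family gene, by 2.27, AT4G16920, a TIR-NBS-LRR resistance gene, by 2.24, and AT3G14280 by 2.19. SEU, which encodes the adaptor SEUSS that joins LUG to DNA-binding proteins, went from 152 ± 2.81 to 120 ± 2.86 (log2 change -0.33, adjusted p = 0.0270), a small fall that was lost when wild-type leaves 3, lug-3 leaves 2 or lug-3 leaves 3 was left out (adjusted p up to 0.0843).

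Of the lists fixed beforehand, all 3 measured genes of flavonoid and anthocyanin synthesis fell in lug-3 leaves. DFR, dihydroflavonol reductase, fell by 2.06 (156 ± 67.4 to 29.5 ± 8.25), and UF3GT, an anthocyanin glycosyltransferase, by 1.38, beside AT4G14090. The camera test gave an adjusted p of 0.0118, and adjusted p = 0.490 with an estimated correlation. This group moved with RNA quality: with the GAPDH ratio as a covariate 2 of the 3 genes remained called, the median log2 change was -1.64 instead of -2.06, and the camera adjusted p was 0.0677. Without the 3 arrays of highest ratio the median was -1.39, with wild-type leaves 1 alone for wild type. DFR was lowest on that wild-type array (88.6, against 157 and 223 on wild-type leaves 2 and 3). This median therefore cannot tell RNA quality from a difference between single arrays. In the cell cycle and DNA replication list 2 of 3 genes rose, the replication helicase subunit PRL (0.82) and the Aurora kinase AUR2 (0.91). The AUR2 signals were low, at most 11.7 in wild-type and 24.9 in lug-3 leaves. The camera adjusted p of this list was 0.0484, and adjusted p = 0.337 with an estimated correlation. It was 0.0592 after quantile normalization, 0.0509 after median centring and 0.153 with the covariate, under which 1 gene stayed called.

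Other lists changed in single members in leaves. JMT, the jasmonate methyltransferase, rose by 1.53 and the thionin gene THI2.1 by 0.77, 2 of 3 measured jasmonate genes. GRX480, a glutaredoxin gene induced by salicylic acid, rose by 1.15, the only call among 3 genes of its list. Among 4 cold and drought genes COR15A rose by 1.48 and COR47 fell by 0.82. LHCB4.2, a light-harvesting protein gene, rose by 0.65, the only one of 6 photosynthesis genes called. Single falls were those of WES1, an auxin-conjugating enzyme gene (-0.88, 1 of 6 auxin genes), WRKY6 (-0.99, 1 of 2 senescence genes), BCAT4 (-0.60, 1 of 2 glucosinolate genes), PLIM2b (-0.56, 1 of 4 pollen genes) and the clock gene GI (-0.59, the only gene tested of 15 on the clock list). No gene was called among 3 flowering time, 4 meristem and polarity, 5 carpel and ovule, 3 petal and stamen and 2 tapetum genes, nor were the heat shock gene ATHSP22.0 (0.58) and the touch-responsive STZ (0.37). The value of STZ turned to -1.04 with the GAPDH covariate. It was -1.41 without the 3 arrays of highest ratio, where wild-type leaves 1 alone stood for wild type. The STZ signal was 2233 on that array, against 175 and 668 on wild-type leaves 2 and 3. Of the 18 different genes with no call in these lists limma put 2 at an unadjusted p under 0.05. The calls of GRX480 and COR15A held when each leaf array in turn was left out, while those of JMT, THI2.1, COR47, LHCB4.2, WES1, WRKY6, BCAT4, PLIM2b and GI were each lost without at least 1 array (adjusted p up to 0.141, for GI). The log2 change of GRX480 was 0.71 without the 3 arrays of highest ratio, with wild-type leaves 1 alone for wild type. Counts adjusted over the list alone were the same except for the tapetum list, in which 1 gene, AT1G75920, then rose. The count of 3993 became 2600 without lug-3 leaves 2, 2581 without lug-3 leaves 3 and 1950 when only the leaf arrays were fitted. The 2 lists past the camera threshold became 1 without wild-type leaves 2, lug-3 leaves 1 or lug-3 leaves 2.

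The second comparison asked the same of flowers. The measured pollen, tapetum and anthocyanin genes fell in lug-3 flowers. BAN, the anthocyanidin reductase gene of the young seed coat, went from 295 ± 62.1 to 4.80 ± 2.76 (log2 change -4.56, SE 0.176, adjusted p = 1.52e-07). The pollen genes PLIM2a and MGH3, which encode a LIM-domain protein and a sperm cell histone H3, fell by 1.98 and 1.71. DFR fell by 3.05 (472 ± 161 to 48.0 ± 9.80) and AT4G14090 by 4.01 (258 ± 106 to 9.52 ± 11.2). In all, 2150 probe sets were called, 943 higher and 1207 lower in lug-3, with 224 and 665 changed by more than 2-fold. The balance depended on the setting: 747 were higher and 1337 lower after median centring, and 2769 higher and 2290 lower with array weights.

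**Figure D1:**
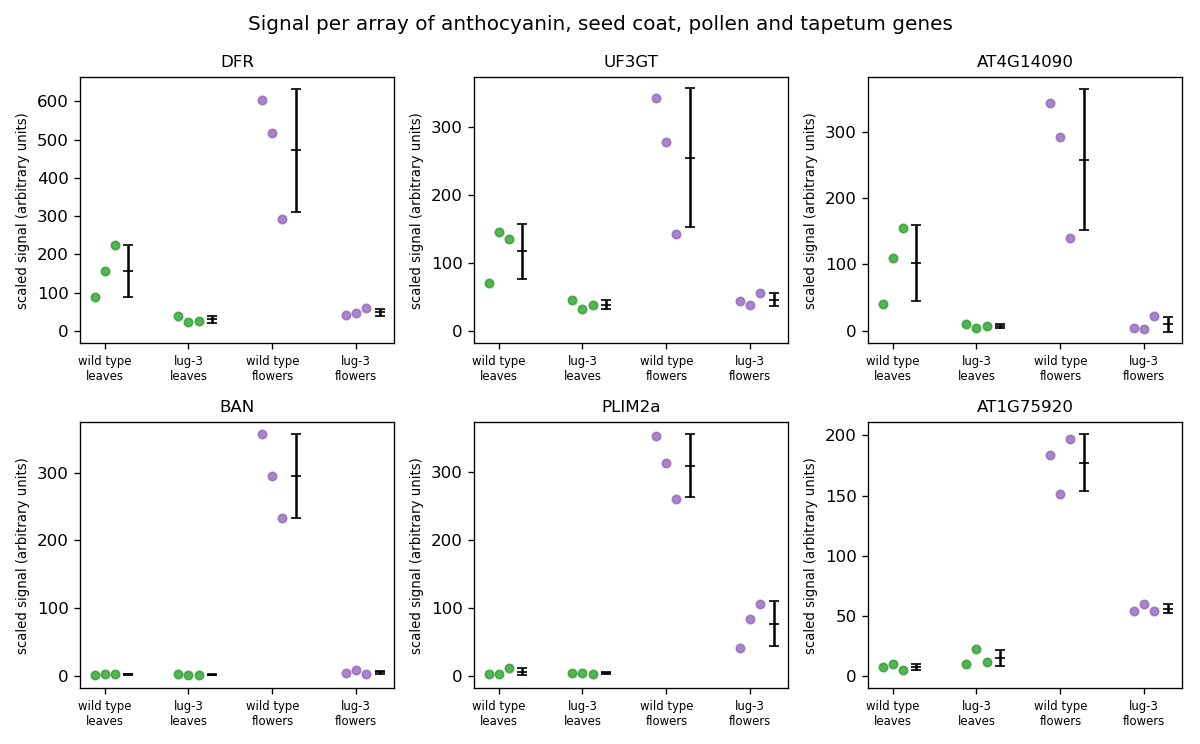
Scaled signal in arbitrary units of DFR, UF3GT, AT4G14090, BAN, PLIM2a and AT1G75920 on each array (points), with mean ± SD beside them, in the 4 groups of 3 arrays. The anthocyanin genes DFR, UF3GT and AT4G14090 lay lower on the lug-3 arrays of both tissues, while BAN, PLIM2a and AT1G75920 had flower signals of 295, 309 and 177 in wild type and 4.80, 76.7 and 55.8 in lug-3.

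The remaining large falls in flowers were those of AT1G56100 (-4.36, 583 ± 113 to 20.8 ± 5.33), AT4G15750, a pectin methylesterase inhibitor-like gene (-4.34, 1582 ± 108 to 72.1 ± 19.1), and AT2G38900, a gene of the potato inhibitor I family of protease inhibitors (-4.18, 297 ± 77.3 to 9.04 ± 5.31). AT5G47350 fell by 4.14 (1083 ± 162 to 54.6 ± 14.6), AT4G19240 by 3.87 and RR22, a response regulator gene, by 2.98 (from 65.1 ± 12.3). AT4G35725 had a log2 change of -3.14. The largest rise was that of CYP71B26, a cytochrome P450 gene, from 33.9 ± 2.30 to 240 ± 12.1 (log2 change 2.56, adjusted p = 4.83e-05). AT4G21650, a subtilase gene, rose by 2.47 (83.3 ± 5.81 to 506 ± 109). AT2G05540, a glycine-rich protein gene, rose by 2.43 with widely spread lug-3 arrays (32.6 ± 5.70 to 299 ± 233), AT3G26070, a plastid fibrillin gene, by 2.37, and the ubiquitin ligase gene PUB19 by 2.33. LTI30, a dehydrin gene, rose by 2.33 (88.1 ± 10.4 to 509 ± 210). AT2G27080 rose by 2.32, AT3G44430 by 2.19 (2.56 ± 0.988 to 40.3 ± 3.33), AT3G47680 by 2.05 and AT4G13050, an acyl-ACP thioesterase gene, by 2.04 (9.50 ± 5.13 to 63.3 ± 17.1). SEU did not pass the test in flowers (log2 change 0.06, adjusted p = 0.754).

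All 4 tested pollen genes, of 24 on their list, fell in lug-3 flowers: besides PLIM2a and MGH3 these were ACT12, a pollen actin gene, and PLIM2b (-1.06). The camera adjusted p was 8.67e-06, and 0.0145 with an estimated correlation. Both tested tapetum genes, of 20 on their list, fell: AT1G75920, a coat lipase gene also called EXL5 (-1.53), and AT5G07230, also called A9 (-1.21). The 3 anthocyanin genes fell, UF3GT by 2.21 (254 ± 102 to 45.8 ± 9.10), with a camera adjusted p of 8.67e-06, and adjusted p = 0.117 with an estimated correlation. Of 5 carpel and ovule genes, BAN and INO, which acts in the outer integument of the ovule, fell (INO -0.71), and SPT, a carpel margin gene, rose by 0.57. The petal growth gene BPEp fell by 1.19 and the polarity gene YAB5 by 0.69, each the only call in its list of 3 and 4 genes. Those lists' medians were positive (0.30 and 0.15), while camera pointed down at an adjusted p of 0.845 for both, and their means were -0.14 and 0.02. GH3.3, an auxin-conjugating enzyme gene, fell by 1.70 (to 69.2 ± 5.60), the only call among 6 auxin genes. The camera adjusted p of that list was 0.0334, and adjusted p = 0.232 with an estimated correlation. It was 0.0624 with the GAPDH covariate and 0.0675 without the 3 arrays of highest ratio.

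Among 3 salicylic acid and defence genes, GRX480 rose by 0.76 and WRKY53 by 1.75 in lug-3 flowers. The camera adjusted p was 0.0334, and adjusted p = 0.334 with an estimated correlation. The 6 photosynthesis genes gave the same pair of values with no member called by limma, 3 at an unadjusted p under 0.05, and a median log2 change of 0.28. LTI30 was the only call of 4 cold and drought genes, AUR1 fell by 0.47 as 1 of 3 cell cycle genes, and GI rose by 0.64. No gene was called among 3 flowering time, 3 jasmonate, 2 glucosinolate and 2 senescence genes, and ATHSP22.0 (0.22) and STZ (1.72) did not pass. STZ did pass with only the flower arrays fitted (adjusted p = 0.0150), with array weights (0.00567), with the GAPDH covariate (0.0152) and without the 3 arrays of highest ratio (0.000288). Of these genes together with SEU and the photosynthesis genes, 19 in number, limma put 6 at an unadjusted p under 0.05. None of the floral homeotic genes was tested. The flower calls of YAB5, SPT, AT5G07230, AUR1, WRKY53, GRX480, BPEp, INO, GI, AT2G05540 and AT2G27080 were each lost without at least 1 flower array (adjusted p up to 0.185, for AUR1). Adjusted over the list alone, 3 defence genes, 2 photosynthesis genes and STZ rose, and 2 auxin, 2 cell cycle and 1 jasmonate genes fell, with other lists as before. The count of 2150 became 1151 without wild-type flowers 1, 1199 without wild-type flowers 2, 1312 without lug-3 flowers 1, 1231 without lug-3 flowers 2 and 5059 with array weights. The 5 lists past the camera threshold became 2 without wild-type flowers 1 or lug-3 flowers 1 and 3 without lug-3 flowers 2.

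The third comparison set wild-type flowers against wild-type leaves. Leaves were taken at growth stage 3.90 and flowers at 6.90. Tissue and stage therefore cannot be told apart in this comparison or in the interaction. Some genes, among them genes of the anther, stood far above their leaf level in flowers, and glucosinolate and photosynthesis genes stood lower. GILT, a thiol reductase family gene, had a signal of 2347 ± 172 in flowers and 9.21 ± 0.506 in leaves (log2 change 7.09, adjusted p = 1.27e-11). BCAT4, which starts the chain elongation of methionine in glucosinolate synthesis, had 71.3 ± 14.6 in flowers and 3035 ± 546 in leaves (log2 change -5.27). Of the tested probe sets 10582 were called, 5897 higher and 4685 lower in flowers. ATA27, an anther beta-glucosidase gene, was 6.69 higher on the log2 scale, AT5G45880 6.72, AT3G28750 6.68 and AT1G72290, a protease inhibitor gene, 6.50. The other lowest were AT4G01390 (-4.92), AT1G30250 (-4.89), AT1G35710, a receptor kinase gene (-4.85), and ECS1 (-4.70). SEU did not differ past the threshold (-0.18, adjusted p = 0.124), though it did after median centring (-0.36, adjusted p = 0.00598).

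All 6 photosynthesis genes were lower in wild-type flowers (LHCB4.2 -2.02, RCA -1.15), with a camera adjusted p of 0.00129 and adjusted p = 0.197 with an estimated correlation. All 5 carpel and ovule genes (BAN 4.88), all 4 pollen genes (PLIM2a 4.55) and all 3 cell cycle genes (AUR2 2.73) were higher, each with a camera adjusted p of 0.0115. With an estimated correlation these were adjusted p = 0.197, 0.115 and 0.115. The 3 anthocyanin genes were higher in flowers (DFR 1.57) with a camera adjusted p of 0.192, and both tapetum genes were higher (AT5G07230 4.59, AT1G75920 3.57). All 3 defence genes (camera adjusted p = 0.0543) and both glucosinolate genes were lower. In wild-type flowers THI2.1 (5.96), JMT (4.17), COR15A (2.62) and COR15B (0.90) were higher, as were GH3.3, YUC6, WES1 and YUC2 of 6 auxin genes, PTL and BPEp of 3 petal and stamen genes, PHV (0.79) and SAG29 (1.72). PDF1.2 (-1.57), LTI30 (-0.94), IAA29 (-0.91), FD (-1.13), SNZ (-2.34) and STZ (-3.17) were lower, while GI and ATHSP22.0 did not pass. Adjusted over the list alone, 1 senescence gene was also lower, with other lists as before. The balance of calls depended on scaling: the median log2 change of all tested probe sets was 0.06 as deposited and moved by -0.17 with quantile normalization and by -0.18 with median centring. The split of 5897 higher and 4685 lower then became 5002 and 6106, and 4759 and 6192.

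The interaction asked whether the change in lug-3 differed between flowers and leaves. For 4110 probe sets it did, with 2063 more positive and 2047 more negative in flowers. HIS1-3, a drought-induced linker histone gene, fell by 2.19 in lug-3 leaves and rose by 1.70 in lug-3 flowers (difference 3.89, SE 0.571, adjusted p = 0.00111). AT2G38240, a jasmonate oxidase gene, rose by 3.02 in leaves, and its flower change was -1.77 (adjusted p = 0.214). The difference was -4.79 (adjusted p = 0.0146). The leaf rise rested on lug-3 leaves 2 and 3 (346 and 355), as lug-3 leaves 1 (19.2) lay within the wild-type range (3.11 to 38.4). In flowers every lug-3 array (28.5 to 75.3) lay below every wild-type array (181 to 195). BAN, AT1G56100, AT5G47350 and AT4G15750 fell in flowers and showed no call in leaves, with differences of -4.50, -4.50, -4.32 and -4.13. Their leaf signals in either genotype were at most 2.84, 11.1, 16.6 and 35.4, which left little room for such a fall in leaves. AT1G80130 (3.46), AT1G22160 (3.25), AT4G18250 (2.95) and AT1G67920 (2.89) fell in leaves. Of these, AT1G22160 rose by 0.63 and AT1G67920 by 0.97 in flowers. The flower signals of AT4G18250 were at most 8.84, which left little room for a fall there. The SEU difference of 0.39 missed the threshold (adjusted p = 0.0553).

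Among the lists, all 3 cell cycle genes had a more negative change in flowers (PRL -0.93, AUR2 -1.53, AUR1 -0.74), with a camera adjusted p of 0.0277 and adjusted p = 0.137 with an estimated correlation. Of the 4 pollen genes, PLIM2a and MGH3 did (-1.79 and -1.41), with a camera adjusted p of 0.0305 and again adjusted p = 0.137 with an estimated correlation. With the GAPDH covariate the camera adjusted p of both lists was 0.0563. Both tapetum genes had more negative changes in flowers (AT1G75920 -2.04, AT5G07230 -1.52), and GI a more positive 1.23. In leaves the signals of PLIM2a, MGH3, AT1G75920 and AT5G07230 were at most 11.5, 10.6, 22.0 and 14.6, which left little room for a fall. The anthocyanin difference did not pass in limma in any of 3 genes, 0 of them at an unadjusted p under 0.05 (camera adjusted p = 0.222). Single members passed elsewhere: GH3.3 (-2.05), THI2.1 (-1.38), YAB5 (-0.90) and BAN had more negative changes in flowers, and LTI30 (2.16), SPT (0.71) and BCAT4 (0.79) more positive ones. Adjusted over the list alone, 3 pollen genes, 1 petal and stamen gene, 2 cold and drought genes and SEU passed. The carpel and the petal lists had positive medians (0.13 and 0.08) with negative means (-0.76 and -0.29) and a downward, uncalled test.

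Families were formed from gene symbols after the data had been examined, and the glycosyl hydrolase group was narrowed to family 9 after its values had been seen. Of 8 autophagy genes of the ATG8 and ATG3 kind, 6 fell in lug-3 leaves (ATG8B -1.11, ATG8C -1.03, ATG8D -0.93), also after quantile normalization and median centring, and 2 fell in flowers. The leaf camera adjusted p was 2.11e-05, and adjusted p = 0.234 with an estimated correlation. With the GAPDH ratio as a covariate 5 fell. Of 10 RALF-like peptide genes, 7 fell in flowers (RALFL25 -2.15, RALFL26 -1.85), under both scalings too, with a camera adjusted p of 1.31e-05 and 0.0407 with an estimated correlation. In the same flower arrays all measured pollen and tapetum genes fell (medians -1.45 and -1.37), and 9 of the 10 RALF-like genes were higher in wild-type flowers than in leaves under each scaling. In lug-3 leaves 4 of them rose and 2 fell. Of 11 glycosyl hydrolase family 9 genes, which encode endoglucanases, 4 fell in flowers (GH9B11 -1.82), under both scalings too, with a camera adjusted p of 0.003, and adjusted p = 0.0798 with an estimated correlation. These falls too stood beside those of all measured pollen and tapetum genes, and 10 of the 11 genes were higher in wild-type flowers than in leaves under each scaling. In leaves 5 rose (GH9B8 1.43, GH9B7 1.41) and 4 after quantile normalization, with a camera adjusted p of 0.0684. The interaction had a camera adjusted p of 0.000163, and adjusted p = 0.0503 with an estimated correlation.

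**Figure D2:**
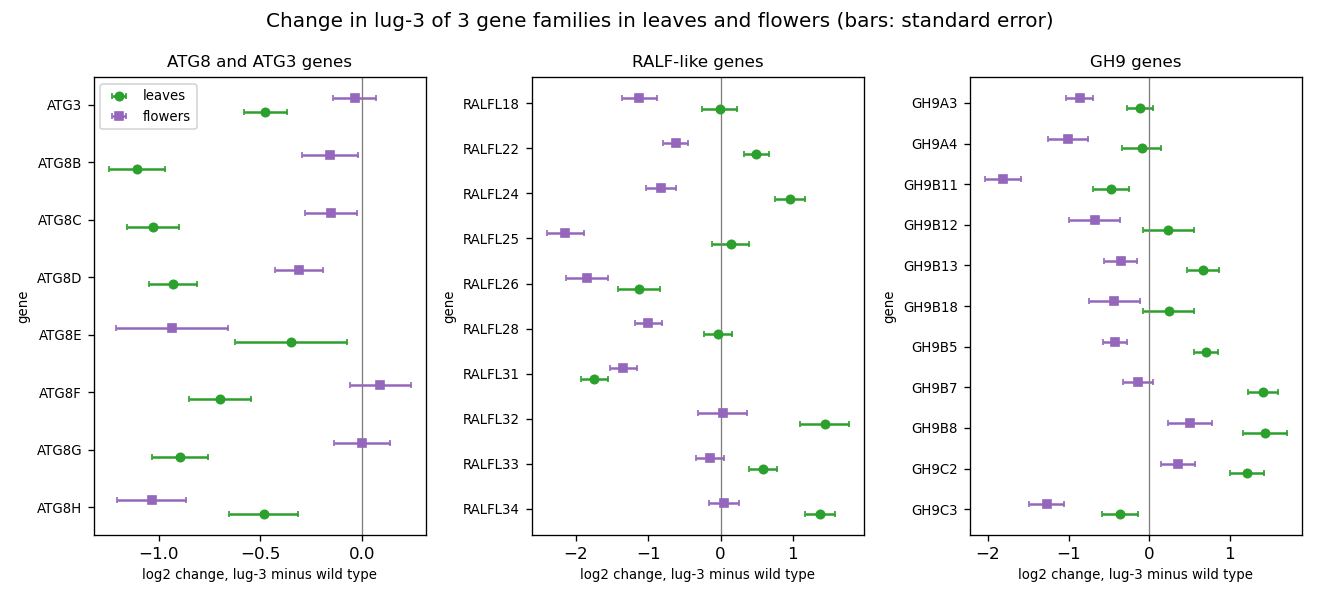
Log2 change in lug-3 against wild type (± SE, n = 3 arrays per group) of each tested gene of the ATG8 and ATG3, RALF-like and glycosyl hydrolase 9 families, in leaves (circles) and flowers (squares). Of the autophagy genes 6 fell in leaves, and of the RALF-like genes 7 fell in flowers, in counts that were the same under both scalings.

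The last comparison asked whether the genes called in lug-3 leaves and flowers were shared. Of 558 probe sets called in both tissues (480 by chance, Fisher's exact test odds ratio 1.25, adjusted p = 5.94e-05), 225 changed in the same direction and 333 in opposite directions. Both comparisons used the same estimate of spread per probe set, which can by itself raise the number called in both. Genes lower in leaves and higher in flowers numbered 195 against 104 by chance (Fisher's exact test odds ratio 2.22, 95% interval 1.87 to 2.63, p = 9.43e-19, adjusted p = 4.71e-18). HIS1-3, AT1G67920, AT4G09760, AT1G22160 and GI were among them. Higher in both were 99 against 107, lower in both 126 against 133, and higher in leaves but lower in flowers 138 against 136, none past the test. The genes lower in both held AT4G19240, AT4G14090, DFR and UF3GT, and those higher in both AT4G21650 and AT4G13050. Across probe sets, which are not independent, Pearson's r of the changes was -0.0094 and Spearman's rho -0.109. The 5 Fisher tests were adjusted together. The 225 became 142 without lug-3 leaves 3, 118 and 114 without wild-type flowers 1 or 2, 127 and 124 without lug-3 flowers 1 or 2, 139 with the GAPDH covariate and 526 with array weights.

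**Figure D3:**
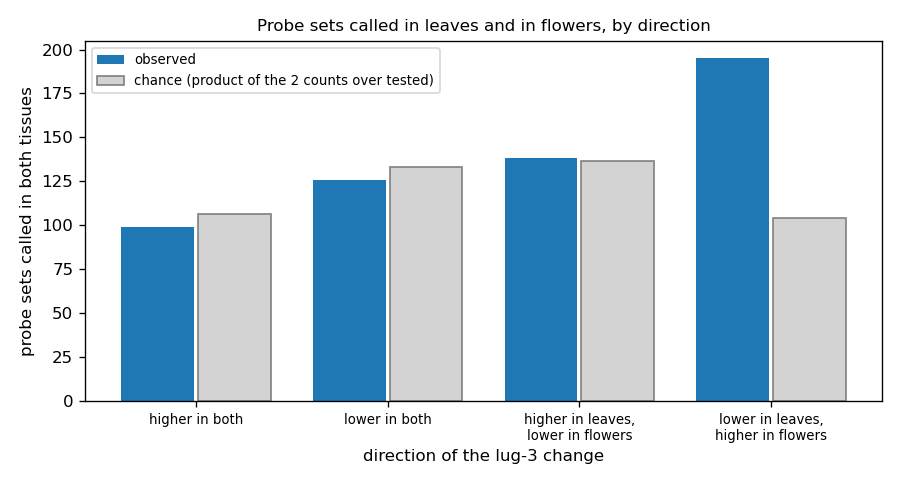
Number of probe sets called in lug-3 against wild type in both tissues for each combination of directions, as observed and as given by chance from the numbers of calls. The 195 probe sets lower in leaves and higher in flowers stood above the 104 given by chance, and the other classes lay near theirs.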

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

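All tests of the 3 patterns weighed in this part were chosen only after the result was seen, except the RNA quality test of the chromosome 4 cluster and the counts of other splits of the arrays; the RNA quality settings themselves were added after the data had been examined.

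The test of the difference between tissues picked out 4110 probe sets whose lug-3 change was not the same in flowers and leaves. The largest positive differences, flowers minus leaves on the log2 scale, were those of HIS1-3 (3.89), AT1G80130 (3.46), AT1G22160 (3.25), AT4G18250 (2.95) and AT1G67920 (2.89). The largest negative differences were those of AT2G38240 (-4.79), BAN (-4.50), AT1G56100 (-4.50), AT5G47350 (-4.32) and AT4G15750 (-4.13). Low leaf signals in both genotypes left BAN, AT1G56100, AT5G47350 and AT4G15750 little room for a fall in leaves. Low flower signals did the same for AT4G18250 in flowers.

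Other splits of the arrays were fitted in the same way. For the difference between tissues 1 of 100 splits, the real one, gave as many as 4110 probe sets. The highest of the others, 2742, came from the split that exchanges the genotypes in flowers alone. The remaining splits mix lug-3 and wild-type arrays within a group, which widens the spread there. The rank of the real split therefore cannot exclude a random division of the arrays. For the 225 calls shared in direction by leaves and flowers, 2 of 100 splits gave as many, the highest of the others 333, from the split that exchanges the genotypes in flowers alone and so counts the opposite calls. Most other splits had an overlap of 0, so this count says nothing about shared direction. The 10 splits of 6 arrays cannot give a share under 0.05. There 1 split, the real one, reached 3993 in leaves (highest other 7), 1 reached 2150 in flowers (highest other 1), and 1 reached 10582 between the tissues (highest other 0). For lists past the camera threshold, 3 splits reached the 2 in leaves (highest other 3) and 1 reached the 5 in flowers (highest other 3).

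Calls of the same direction in both tissues lay close together on chromosome 4. Of 9815 tested genes 113 had such calls, and 15 lay among 200 neighbours between AT4G11160 and AT4G16146 (1.02% of genes had them elsewhere), more than in any of 10000 random placements (highest 13, permutation p = 1e-04, the smallest possible), as a stretch of the chromosome that differs between the lines would need. Sequence next to the LUG gene would not account for the cluster, since 0 of the 15 lay among the 200 genes around LUG, which held 3 such calls against 2.30 by chance (one-sided Fisher's exact test, p = 0.406). With the RNA quality covariate 14 calls still clustered (permutation p = 1e-04), which argues against RNA quality as the whole cause. The fit without the 3 arrays of highest ratio cannot weigh on this, since its leaf calls rest on a single wild-type array. A stretch that differs between the lines stays a hypothesis, found and tested on the same data. AT4G14090, whose fall is the largest of the anthocyanin genes, lies in it. So do GILT and AT4G13050, the latter named above as higher in both tissues (2.27 in leaves, 2.04 in flowers). An effect of lug-3 itself on neighbouring genes stays open and was not tested.

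Genes lower in lug-3 leaves and higher in lug-3 flowers exceeded chance, with an odds ratio of 2.22. The lowest odds ratio under the RNA quality settings was 3.44 (95% interval 2.89 to 4.09), that of the covariate fit. This value cannot decide for or against RNA quality. The GAPDH ratio of lug-3 minus wild type was -1.09 in leaves and 0.435 in flowers. An error in a gene's fitted slope would therefore push its leaf and flower changes apart. The other setting, without the 3 arrays of highest ratio, cannot weigh on RNA quality either, since its leaf calls rest on a single wild-type array. The lowest odds ratio under the other scalings of the arrays was 1.99 (1.68 to 2.34), which argues against scaling. A different role of LUG in the tissues, the contrast that the design names, stays open and was not tested. Tissue and growth stage (3.90 for leaves, 6.90 for flowers) cannot be told apart here.

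All 6 tested pollen and tapetum genes fell in lug-3 flowers. With the RNA quality covariate 6 of the 6 were still called and lower, which argues against RNA quality, although AT5G07230 missed the threshold without the 3 arrays of highest ratio at a log2 change of -1.27 (adjusted p = 0.0504). A smaller share of anther tissue in the lug-3 flower samples and a change of transcription within the anther cannot be told apart here, since the medians of 4 pollen and 2 tapetum genes differed by 0.0824 while the single genes ran from -1.06 to -1.98. BAN, a seed coat gene, had a log2 change of -4.56, a larger fall than each of theirs. As BAN is not an anther gene, its fall cannot decide for or against a smaller share of anther tissue. The cause of the fall of BAN was not tested. A direct effect of lug-3 on these genes stays open and was not tested.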

How the results depend on the processing

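The covariate and the fit without the 3 arrays of highest 3'/5' ratio were chosen only after the data had been seen. The latter kept only wild-type leaves 1 for wild type in leaves. Of 36 called values of named genes in leaves 22 kept their call and sign under every alternative run at an adjusted p of 0.05, and of 36 in flowers 25. For tissue and interaction only the 10 largest changes each and SEU were rerun, and the 10 kept theirs; no called gene rerun changed sign. At 0.01 AT2G38240 lost its interaction call (adjusted p = 0.0146). The cause of the changes listed here was not tested, except that fewer arrays leave fewer degrees of freedom. Array number limits the precision, and 3.81% to 5.73% of the probe sets of an array had a signal below 1.

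Calls in leaves (3993) were 1950 with only the groups compared in the fit and 1877 at adjusted p under 0.01, and 2581 to 4014 when single arrays were left out. Calls in flowers (2150) were 5059 with array weights, 969 at 0.01, and 1151 to 1872 when single arrays were left out. The interaction (4110) had 1785 at 0.01. The overlap in the same direction (225) was 526 with array weights, 72 at 0.01, 139 with the RNA quality covariate and 114 to 274 when single arrays were left out. With the covariate leaves had 2816, flowers 2280, tissue 10200 and the interaction 2987, and without the 3 arrays 3028, 2383, 9351 and 3564.

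The 2 lists past the camera threshold in leaves became 1 with pseudocount 32, the stricter filter on dim probe sets, quantile normalization, arrays centred on their median, only the groups compared, the trend option and the replicate block. They became 0 with the correlation estimated (1 of 12 at an unadjusted p under 0.05 in camera), 0 with the covariate (3), and 1 to 2 when single arrays were left out. The 5 in flowers became 7 with pseudocount 32, no filter and quantile normalization, 6 with the stricter filter, centring and trend, 4 with the block and only the groups compared, 1 with the correlation estimated and 2 to 6 when single arrays were left out.

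Values with no call under the settings used for the results above changed sign as follows. In leaves, pseudocount 1 gave PTL -0.022 and BPEp -0.026, pseudocount 32 gave FD -6.99e-05, quantile normalization gave PTL -0.090, FD -0.032 and BPEp -0.020, and array weights gave PTL -0.024 and BPEp -0.11. Array weights in flowers gave IAA29 0.14, YAB3 0.054 and SNZ 0.025. The covariate in leaves gave SAG29 0.14, PTL -0.18, LTI30 -0.50, FD -0.013, WRKY53 -1.05, STZ -1.04 and PLIM2a 0.33. Without the 3 arrays, against a single wild-type leaf array, leaves gave SAG29 0.45, PTL -0.37, LTI30 -0.42, FD -0.26, WRKY53 -1.24, INO 0.12, BAN 0.012, PLIM2a 0.070 and STZ -1.41. In the same fit flowers gave YAB3 0.085 and JMT -0.049. With single arrays left out, leaf values ranged over SAG29 -0.89 to 0.054, SAG101 -0.53 to 0.066, PTL -0.21 to 0.19, LTI30 -0.29 to 0.46, FD -0.28 to 0.20, WRKY53 -0.31 to 0.76, STZ -0.55 to 1.26, BPEp -0.15 to 0.44 and PLIM2a -0.33 to 0.075. Flower values ranged over IAA29 -0.55 to 0.023, YAB3 -0.19 to 0.13, JMT -0.049 to 0.31 and SNZ -0.41 to 0.12.

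Calls were also lost when single arrays were left out, named here with the highest adjusted p. In leaves these were WES1 (wild type 1 or 3, lug-3 2 or 3; 0.0756), BCAT4 (wild type 2 or 3, lug-3 2 or 3; 0.0892), LHCB4.2 (wild type 1 or 3, lug-3 2 or 3; 0.0935), COR47 (wild type 1 or 3, lug-3 1 or 3; 0.0873), THI2.1 (lug-3 2 or 3; 0.0706), SEU (wild type 3, lug-3 2 or 3; 0.0843), JMT (wild type 2, lug-3 2 or 3; 0.0850), PLIM2b (wild type 1 or 3, lug-3 2 or 3; 0.106), GI (all but wild type 2; 0.141) and WRKY6 (all but wild type 2; 0.130). In flowers YAB5 (0.106), AUR1 (0.185), WRKY53 (0.118), GRX480 (0.131) and AT2G05540 (0.0952) lost theirs without any single array but lug-3 3, and GI without each of the 6 (0.139). Others there were SPT (wild type 2, lug-3 1; 0.0553), AT5G07230 (wild type 3, each lug-3 array; 0.0883), BPEp (wild type 1 or 2, lug-3 2 or 3; 0.0931), INO (wild type 1 or 3, lug-3 2; 0.0710) and AT2G27080 (wild type 1, lug-3 1 or 2; 0.0597). Calls were gained in leaves by GH3.3 (wild type 3), SAG29 (wild type 1), PDF1.2, AGL24 and PHV (wild type 2) and AT1G75920 and COR15B (lug-3 1), and in flowers by YUC6 (wild type 3) and PSAN and LHCB4.2 (wild type 3, lug-3 3). With the covariate, calls were lost in leaves by UF3GT (-1.10, adjusted p = 0.0880), AUR2 (0.62, 0.115), AT2G20670 (1.82, 0.0682), BCAT4, LHCB4.2, SEU, PLIM2b and GI. Without the 3 arrays calls were lost in flowers by AT5G07230 and BPEp (-1.18, adjusted p = 0.0663). In leaves, against a single wild-type array, the log2 change was -0.77 for UF3GT, 0.55 for AUR2 and 0.71 for GRX480.

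Calls lost under the other alternatives are given with their adjusted p. In leaves, pseudocount 1 lost GI (0.0511) and WRKY6 (0.0552), no filter lost GI (0.0555) and WRKY6 (0.0639), quantile normalization lost BCAT4 (0.0534), LHCB4.2 (0.0647), SEU (0.0737) and GI (0.0666), and array weights lost GI (0.0829). Only the groups compared in the fit lost WES1 (0.0621), BCAT4 (0.0685), COR47 (0.0675), THI2.1 (0.0710), SEU (0.113), JMT (0.0907), PLIM2b (0.0657), GI (0.143), WRKY6 (0.141) and AUR2 (0.0573). In flowers, pseudocount 1 lost AT5G07230 (0.180), BPEp (0.142), AUR1 (0.0697) and GI (0.0664), no filter lost AUR1 (0.0590), WRKY53 (0.0529) and GI (0.0578), median centring lost GRX480 (0.0507) and GI (0.0603), the robust option lost AUR1 (0.0507), and only the groups compared lost AUR1 (0.0621) and AT2G05540 (0.0565). Calls gained in flowers were those of THI2.1, AUR2, PSAN, LHCB4.2 and STZ under several alternatives, COR15A (0.00979) and COR15B (0.00896) with only the groups compared, YUC6 and LHCB4.1 with array weights, and SAG101 under both RNA quality settings. In leaves AGL24 gained a call with pseudocount 32 and, like JAG, with the GAPDH covariate. The SEU interaction passed under pseudocounts 1 and 32, the stricter filter, the trend option and array weights.

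With the replicate block leaves had 3426 calls, flowers 1788, the tissues 10593, the interaction 3588 and the overlap 174. The adjusted p then lay above 0.05 for AT5G07230 (0.0611), BPEp (0.0571), AUR1 (0.0855) and GI (0.0962) in flowers and BCAT4 (0.0705), LHCB4.2 (0.0748), SEU (0.0764), PLIM2b (0.0565) and GI (0.0828) in leaves, and below it for THI2.1 in flowers (0.0386). Between genotypes, leaf deviations correlated by 0.18 for replicates 1 and by -0.13 to -0.09 for 1 with 2 or 3. Among 2 and 3 the values were 0.03 to 0.10. A batch shared by leaf replicates 1 stays open. Same-number flower arrays gave -0.06 to 0.02. Camera has no robust option, so none was run for lists.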

Other observations

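All families in this part were formed from gene symbols only after the data had been examined, and the likeness of arrays was computed after the calls had been seen. Ubiquitin-conjugating enzyme genes fell in lug-3 leaves, 6 of 11 as deposited and after median centring and 4 after quantile normalization, among them UBC29, UBC30 (-0.48) and UBC32 (-0.46). The camera adjusted p was 0.0401, and adjusted p = 0.234 with an estimated correlation; with the GAPDH ratio as a covariate 2 fell. Among TRICHOME BIREFRINGENCE-LIKE genes, which acetylate cell wall polymers, 7 of 18 rose in leaves as deposited and after median centring, and 5 after quantile normalization (TBL45 1.74, TBL26 1.33), while TBL38 fell by 1.72; the camera adjusted p was 0.0684.

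Sugar transporter genes of the SWEET family fell in lug-3 flowers, 5 of 14 under each scaling (SWEET8 -1.42, SWEET14 -1.34), while SWEET10 rose by 0.53 as deposited. The camera adjusted p was 0.0356, and adjusted p = 0.290 with an estimated correlation. It was 0.152 with the GAPDH covariate. In the same flower arrays all measured pollen and tapetum genes fell (medians -1.45 and -1.37), and 10 of the 14 SWEET genes were higher in wild-type flowers than in leaves as deposited, and 9 under the other scalings. Of 69 chloroplast-encoded probe sets, 14 rose and 1 fell in lug-3 leaves as deposited and after median centring, and 12 and 1 after quantile normalization. The camera adjusted p was 0.0306, and adjusted p = 0.620 with an estimated correlation. The fit without the 3 arrays of highest 3'/5' ratio keeps a single wild-type leaf array. It cannot settle whether these counts depend on RNA quality. In wild-type flowers 43 were lower and 4 higher than in leaves.

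The lug-3 flower arrays were more like leaf arrays than the wild-type flower arrays were. Their mean Spearman's rho with the wild-type leaf arrays was 0.757, 0.757 and 0.738, against 0.674, 0.678 and 0.691 for wild-type flowers.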
